A study of Marmota flaviventris with 43 samples.

How the data were processed

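Whole blood of yellow-bellied marmots (Marmota flaviventris), a ground-dwelling squirrel, was profiled by RNA sequencing in 43 samples. The series labels 16 samples as dispersers, animals that later left their birthplace, and 27 as residents. Per the labels' protocols, RNA came from blood kept in a stabilising solution, globin transcripts were depleted, and pooled libraries were sequenced on 1 of 2 Illumina models. The series' design text calls the dispersers yearlings, and the ages of the residents are not given in the sources used here. Neither are the lane, instrument, sex and date of each sample. Nothing in the labels states that the resident samples came from different animals or that no animal is in both groups, so p-values measure the spread between samples.

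Per the submitters' processing notes, the tools were Trim Galore 0.3.1, TopHat2 2.1.0, HTSeq and limma, with no role or order stated. The genes carry Ensembl IDs, per the file headers. No label, header or processing note names the genome build or the annotation's organism or release. The prefix of the IDs, ENSSTOG in those given below, was not used to name an organism. The deposited count table holds whole-number counts for 22389 genes, of which 2039 had no count in any library, with a mean length and a GC fraction per gene, per the file headers. The length column has a median of 156.6 bases, and what it averages over is not stated. The authors' normalized table holds log2 values for 11381 genes. A comparison with the counts showed that these values equal log2(RPKM + 0.5) plus a constant per library, with a largest deviation of 3.9e-08, where RPKM uses the length column. The genes the authors kept had at least 10 counts in 11 or more libraries, and those left out had that count in at most 11.

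The authors' regressed table holds log2 residuals centred on 0 per gene. The difference between the normalized values, centred per gene, and the regressed values had a rank of 5, so 5 terms were removed. Of these terms, 2 take exactly 2 values over the libraries. No other 2-valued term with at least 3 libraries at each value was found. The remaining 3 are called continuous below, but whether they take only a few values was not tested. No source used here names the 5 terms, and the first 2-valued term is called the first removed term below. The recovery of such terms was tested on simulated data, where 5 of 5 terms and 2 of 2 2-valued ones were found.

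Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 10921 genes. Libraries were scaled by TMM, and groups were compared by the robust quasi-likelihood test with no covariate and Benjamini-Hochberg adjustment at 0.05. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic, and 95% intervals from the t distribution, so both are approximate. The authors' log2 tables were compared with limma 3.58.1, using a mean-dependent prior variance. In the regressed values the residual degrees of freedom are too high, because the 5 terms were fitted beforehand. Group differences in them are also reduced, because the part of the group contrast inside the terms is missing. The median absolute log2 difference was 0.123 in the regressed values. With the terms and the group fitted together to the normalized values it was 0.173. Total counts, genes detected and the share of counts in the 10 most abundant genes were compared by two-sided permutation tests with 100000 resamples, and within the values of the first removed term by exact permutation tests.

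In simulated counts drawn from a negative binomial model with the means and library sizes of this comparison, 200 of the genes were changed. At adjusted p 0.05 edgeR recovered 27.7% of the genes changed 1.5-fold, 70.3% of those changed 2-fold and 96.9% of those changed 4-fold, over 10801 genes tested. Where the changes were put into the real counts under shuffled labels, with 10911 genes tested, it recovered 20.9%, 71.9% and 98.4%. Each simulation was run 1 time, and 9 unchanged genes were called in the first and 0 in the second.

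Groups, tests and a first set of alternatives were fixed before the data were examined. These alternatives were other scaling factors, no filter, another filter, DESeq2 1.42.0, limma-voom with quality weights, a rank-sum test, surrogate variables from sva 3.50.0, 2 principal components, the log2 total count, GC and length trends removed as offsets, other thresholds, and each library left out in turn. With the fit without covariates, 12 sets of covariates or offsets were fitted to all 43 libraries by edgeR. Of these, 7 use the removed terms and were chosen after seeing the data, as were the filter at a CPM of 5, the fits within each value of the first removed term, the fit without the library with the most genes detected, and the limit of 0.7 on the TMM factor.

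The files give gene IDs and do not pair them with names. None of the 22389 IDs matched the reference table of 34400 marmot genes (0 matched; assembly mMarFla1.hap1). The 33 lists of pathway and cell type genes fixed in advance, the scores of these lists, the residual globin share and the alternatives that use blood cell markers or globins were therefore not run. The rule for named genes, which took genes with a symbol, named none. The 4 IDs given below are the 2 with the smallest unadjusted p in each direction and were chosen after their values were seen. All 903 pairs of libraries differed by more than sampling noise, with a smallest chi-square of 22.8 per degree of freedom over genes with at least 20 counts in the pair.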

Results

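Blood transcript counts were compared between 16 samples from dispersers, yearlings that had not yet left per the series' design text, and 27 samples from residents. Total counts ranged from 4592338 to 15066518 among dispersers and from 4725409 to 15237506 among residents. Dispersers averaged 8166010 counts ± 2837345 (SD, n = 16) and residents 7854047 ± 2421067 (SD, n = 27). The difference in means did not pass the test (two-sided permutation test, p = 0.694, adjusted p = 0.694 over 3 measures). Genes with at least 1 count numbered 13789 ± 554 (SD, n = 16) in dispersers and 14132 ± 1113 (SD, n = 27) in residents (permutation test, p = 0.244, adjusted p = 0.365). Without resident replicate 8, residents had 13947 ± 576 (SD, n = 26; permutation test, p = 0.390). The 10 most abundant genes took 17.6% ± 7.53 (SD, n = 16) of the counts in dispersers and 14.1% ± 6.81 (SD, n = 27) in residents (permutation test, p = 0.133, adjusted p = 0.365).

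**Figure D1:**
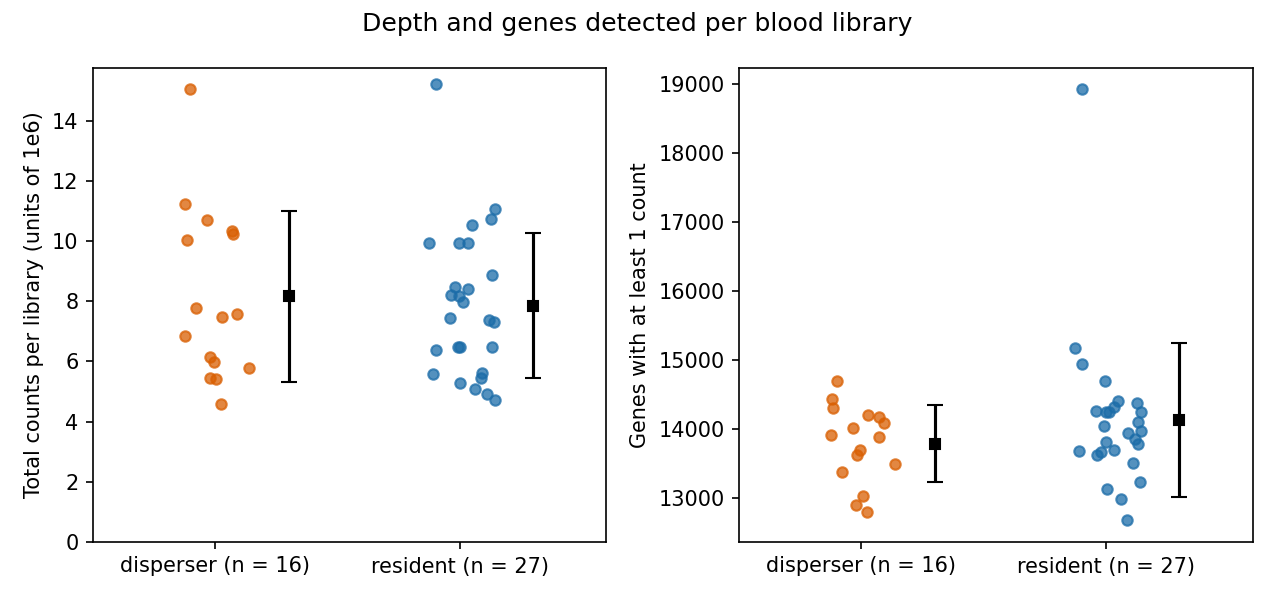
Each point is 1 blood library, with total counts on the left and the number of genes with at least 1 count on the right; squares and bars are the mean ± SD of 16 dispersers and 27 residents. The groups overlap in both measures, and resident replicate 8 stands apart with 18929 genes detected.

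The libraries differed from each other along axes other than the groups. The first principal component of log2 CPM held 42.2% of the variance, of which the group accounted for 0.137% and the first removed term for 57.2%. The second component held 14.03%, of which the group accounted for 1.00%. The first removed term had the value 1 in 21 libraries (9 dispersers, 12 residents) and 0 in 22 (7 dispersers, 15 residents), with no difference between the groups by Fisher's exact test (two-sided, p = 0.536). Libraries at 1 averaged 9344341 counts ± 2740260 (SD, n = 21) and those at 0 averaged 6658375 ± 1487134 (SD, n = 22; permutation test, p = 0.00016, adjusted p = 0.0004 over 5 measures). Their count-weighted mean GC content was 55.0% ± 0.43 (SD, n = 21) and 52.7% ± 1.37 (SD, n = 22; permutation test, p = 2e-05, the smallest that these permutations can give, adjusted p = 0.0001).

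**Figure D2:**
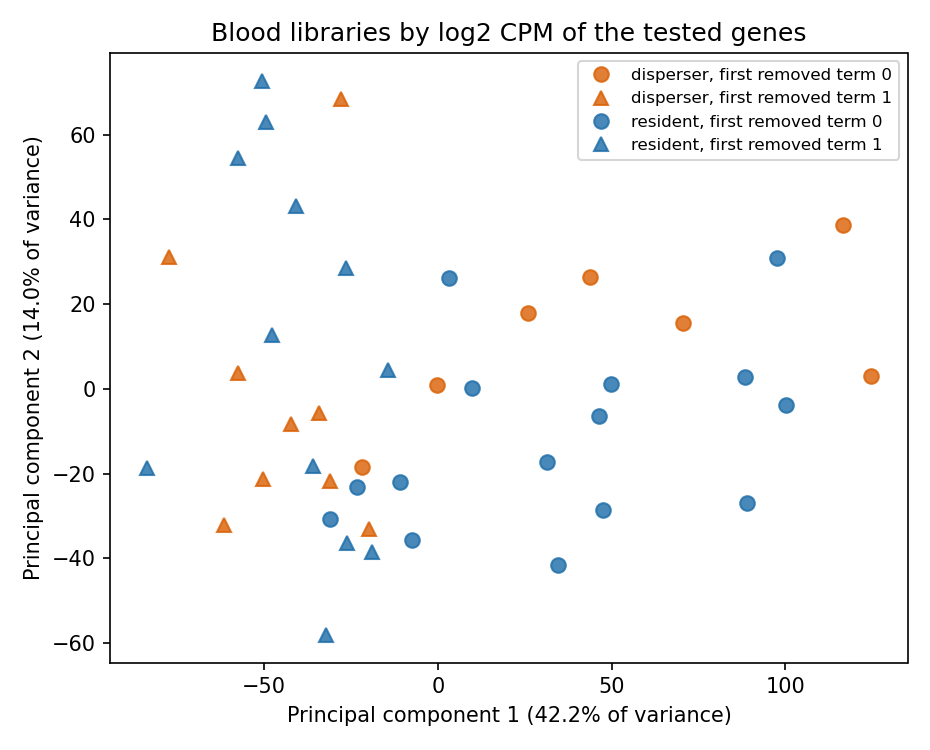
Each point is 1 library placed by the first 2 principal components of log2 CPM over 10921 genes, with 42.2% and 14.03% of the variance on the axes; color gives the group and shape the value of the first removed term. Dispersers and residents are mixed, while libraries at 1 of the term lie mostly to the left.

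The library measures were also compared within each value of that term, a division chosen after seeing the data, and 0 of the 12 tests over 6 measures passed an adjusted p of 0.05. Among libraries at 0, the 10 most abundant genes took 18.9% ± 6.17 (SD, n = 7) of the counts in dispersers and 11.7% ± 4.04 (SD, n = 15) in residents (exact permutation test, p = 0.00735, adjusted p = 0.0882 over 12 tests). Among libraries at 1 the shares were 16.5% ± 8.66 (SD, n = 9) and 17.2% ± 8.40 (SD, n = 12; exact permutation test, p = 0.873, adjusted p = 0.935). The difference between these 2 contrasts was not tested. Total counts did not pass the test at either value (exact permutation tests, p = 0.384 at 0 and p = 0.652 at 1). Genes detected numbered 13604 ± 530 (SD, n = 7) in dispersers and 14353 ± 1355 (SD, n = 15) in residents at 0 (exact permutation test, p = 0.0603), and 14026 ± 502 (SD, n = 14) in residents without replicate 8 (exact permutation test, p = 0.0884). At 1 the exact permutation test gave p = 0.782.

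The comparison of dispersers with residents addressed whether blood gene expression shifts before animals leave their birthplace. No gene differed between the groups past the threshold. With edgeR's quasi-likelihood test, 0 of 10921 genes had an adjusted p under 0.05, 0.1 or 0.2, and the smallest adjusted p was 0.9998. At an unadjusted p under 0.05 there were 284 genes, 122 higher and 162 lower in dispersers, where uniform p-values would give 546. The median absolute log2 fold change was 0.12, the median standard error 0.22, and 39 genes had a fitted change of more than 2-fold. The common biological coefficient of variation was 52.1%. The 95% interval of the fold change lay inside 2-fold for 89.7% of genes, inside 1.5-fold for 52.7% and inside 4-fold for 99.7%. The 2-fold share was 57.3% without a filter, 67.4% and 78.5% in the libraries at 0 and at 1 of the first removed term, and 96.7% with surrogate variables. In 1 simulation of this comparison, with 10801 genes tested, 27.7% of 1.5-fold changes and 96.9% of 4-fold changes were recovered. Most 1.5-fold changes were thus missed with 200 genes changed. Recovery at an adjusted p depends on how many genes change, and other numbers were not simulated.

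DESeq2 also gave 0 genes at adjusted p 0.05 and 541 of 20350 at an unadjusted p under 0.05, over more genes than the 10921 of edgeR, limma-voom with quality weights 0 and 1662, and the rank-sum test 0 and 286. Without a filter on low counts edgeR gave 1 gene, and with 2 principal components as covariates it gave 2 (smallest adjusted p = 0.0141 and 0.0495). The balance of directions moved with the scaling. Of the genes at an unadjusted p under 0.05, 60 were higher and 302 lower when libraries were scaled by total count, which shifted the median log2 fold change of all genes by -0.12. With GC and length trends removed as offsets, 192 were higher and 419 lower. The balance also moved with the covariates, to 708 higher and 502 lower with the 5 removed terms, 784 and 542 with the first and the 3 continuous terms, and 316 and 222 with surrogate variables.

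**Figure D3:**
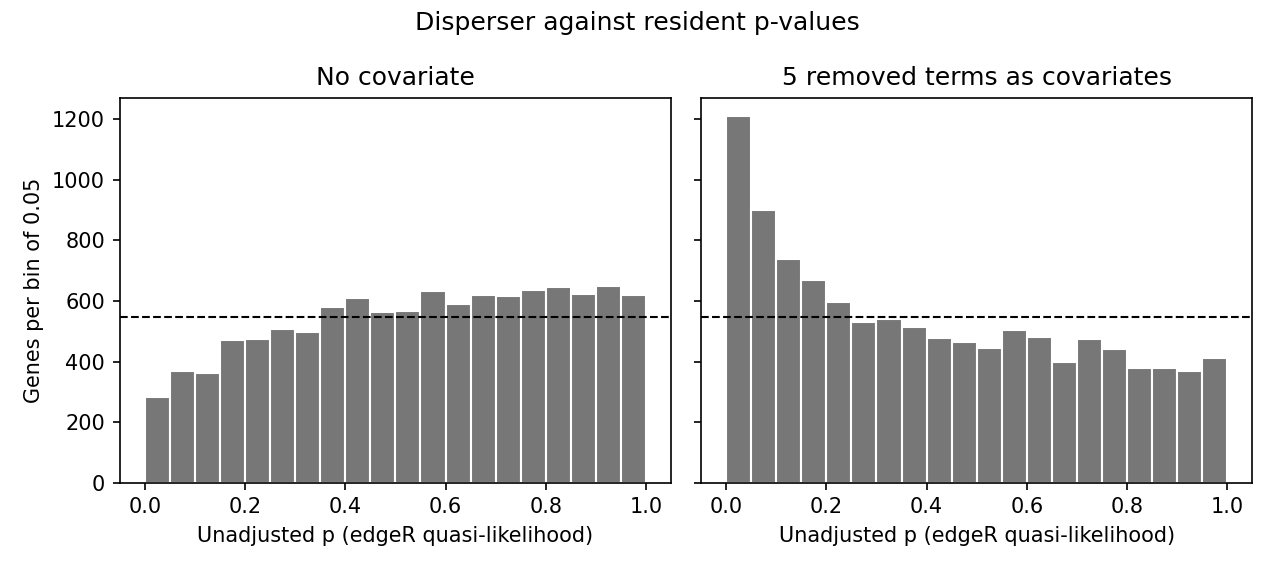
Histograms of unadjusted edgeR p-values over 10921 genes in bins of 0.05, without covariates on the left and with the 5 removed terms as covariates on the right; the dashed line is the number per bin that uniform p-values give, 546. The lowest bin holds 284 genes on the left and 1210 on the right.

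Abundance and GC content were related to the precision of the fold changes. The tested genes were ranked and divided into 5 classes of equal size. In the class with the lowest abundance the interval lay inside 2-fold for 80.5% of genes, with a median standard error of 0.28. In the 4 classes above it the share was between 89.7% and 94.1%. In the class with the highest GC content, at 59.3% or more, the share was 78.4%, with a median standard error of 0.29. Without covariates the median log2 fold change of the 5 GC classes ran from -0.04 to 0.04. With the 5 removed terms it ran from 0.15 in the class with the lowest GC content to -0.07 in that with the highest.

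The files do not pair the gene IDs with names. The genes with the smallest unadjusted p in each direction are given by ID, and none of the 4 passed the threshold (edgeR, adjusted p = 0.9998 for each). ENSSTOG00000009118 averaged 4.76 CPM ± 1.45 (SD, n = 16) in dispersers and 7.15 ± 2.01 (SD, n = 27) in residents. Its log2 fold change was -0.58 (SE 0.14, edgeR unadjusted p = 0.000119), with 14 of 16 dispersers below the resident median. ENSSTOG00000014731 averaged 5.66 CPM ± 4.12 (SD, n = 16) and 15.3 ± 13.8 (SD, n = 27), a log2 fold change of -1.43 (SE 0.39), with 13 of 16 dispersers below the resident median. ENSSTOG00000009560 averaged 19.6 CPM ± 21.9 (SD, n = 16) in dispersers and 8.10 ± 4.89 (SD, n = 27) in residents, a log2 fold change of 1.28 (SE 0.34), with 11 of 16 dispersers above the resident median. ENSSTOG00000028876 averaged 3.88 CPM ± 10.2 (SD, n = 16) and 1.12 ± 0.81 (SD, n = 27), a log2 fold change of 1.77 (SE 0.51), although only 5 of 16 dispersers lay above the resident median. This last value rested on disperser replicate 1, without which it was 0.30. DESeq2 gave 0.25 for ENSSTOG00000028876 (unadjusted p = 0.55), and limma-voom gave 0.30 for ENSSTOG00000009560 (unadjusted p = 0.348), for which the rank-sum test gave an unadjusted p of 0.117.

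At 0 and at 1 of the first removed term, the log2 fold changes of ENSSTOG00000009118 were -0.54 and -0.59, and those of ENSSTOG00000014731 were -1.87 and -0.74. ENSSTOG00000009560 had 1.94 and 0.36, and ENSSTOG00000028876 had 2.47 and 0.39. Disperser replicate 1, on which the value of ENSSTOG00000028876 rested, is 1 of the 7 dispersers at 0. The fit at 0 was not repeated without it. By limma, the difference for ENSSTOG00000009118 was -0.56 in the authors' normalized values and -0.33 in the regressed values (unadjusted p = 0.00786), and that for ENSSTOG00000014731 was -1.21 and -0.81 (unadjusted p = 0.0236). ENSSTOG00000009560 had 0.77 and 0.32 (unadjusted p = 0.306), and ENSSTOG00000028876 had 0.34 and 0.31 (unadjusted p = 0.263). Each p is from the regressed values, in which group differences are reduced. With the 5 terms as covariates, edgeR gave ENSSTOG00000009118 -0.48 and ENSSTOG00000014731 -1.33 (unadjusted p = 0.00453 and 0.0058). It gave ENSSTOG00000009560 0.85 and ENSSTOG00000028876 1.71 (unadjusted p = 0.0262 and 0.0102). None of the 4 passed the threshold in that fit.

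The authors' log2 tables gave no gene past the threshold either. By limma, the normalized values gave 0 of 11381 genes at adjusted p 0.05 and 279 at an unadjusted p under 0.05, of which 133 were higher and 146 lower in dispersers. The regressed values gave 0 genes at adjusted p 0.05 (smallest 0.751) and 730 at an unadjusted p under 0.05. Of these, 499 were higher and 231 lower, where uniform p-values would give 569 genes. With the 5 terms and the group fitted together, the normalized values gave 0 and 1206. Across the 10921 genes tested in both, which are not independent replicates, the edgeR fold changes correlated with those of the normalized values at r = 0.833 and with those of the regressed values at r = 0.424. The direction was shared by 87.9% and 62.9% of these genes. Of the 284 genes at an unadjusted p under 0.05 by edgeR, 70 were also among the 704 of all 10921 genes in the regressed values. Both sets come from the same libraries, so this overlap is not independent support for a group difference.

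**Figure D4:**
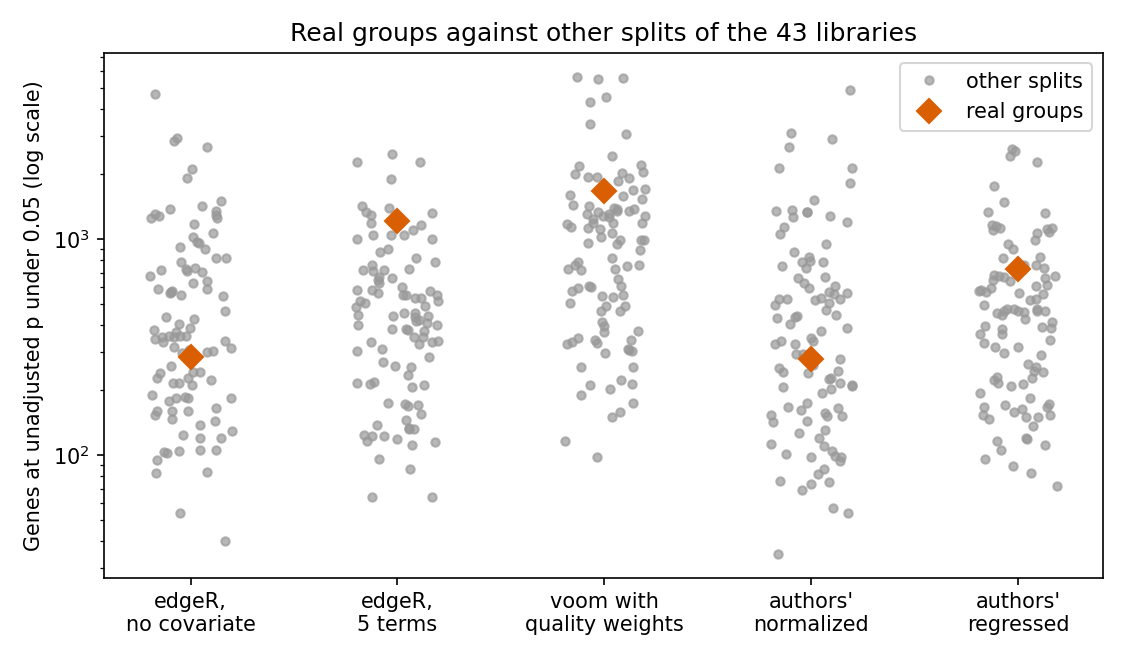
Number of genes at an unadjusted p under 0.05 (log scale) for the real groups (diamonds) and for 99 other random splits of the 43 libraries into 16 and 27 (points), in 5 kinds of fit. In each fit the real count lies inside the range of the other splits.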

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

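The fits with the removed terms, those within a value of the first removed term, the CPM limit of 5, the TMM limit and the fit without the library with the most genes detected were chosen after seeing the data. Alternatives that need gene names were not run, and 0 libraries lay under the median total divided by 3. The planned filter of a CPM of at least 1 in 16 libraries kept 11327 genes, more than the 10921 of filterByExpr.

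The count past the threshold was 0 in 23 of 26 alternatives, of which 3 are other tests and 2 looser thresholds, and in the 43 fits that left out 1 library. It was 1 without a filter, 1 without a filter and without resident replicate 8, and 2 with 2 principal components. The gene called without a filter had counts in 4 libraries (3 dispersers, 1 resident), with 53.1% of them in disperser replicate 6. Both genes called with 2 principal components had an adjusted p of 0.9998 in the fit without covariates.

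The count at an unadjusted p under 0.05, 284 without covariates, ranged from 221 to 421 with 1 library left out. It was 2020 without a filter and 882 when resident replicate 8 was also left out, where more genes were tested. DESeq2 gave 541 over 20350 genes and limma-voom with quality weights 1662. Among the 12 sets of covariates or offsets it ranged from 262 to 1445. It was 538 with 5 surrogate variables, 1232 with 2 principal components, 611 with GC and length offsets, 581 with the 3 continuous removed terms, 1326 with these and the first removed term, 1210 with all 5 terms, and 1445 with all 5 terms and the offsets. The first removed term alone (341), the second alone (262) and both (365) moved it by less than 1.5 times. It was 877 in the libraries at 0 of the first removed term, 307 in those at 1 and 474 without the 6 libraries with a TMM factor under 0.7. In the authors' normalized values it rose from 279 to 1206 with the 5 terms. Tests of the edgeR count with the 5 terms, of the limma-voom count, of the 2 genes called with 2 principal components and of the fit without a filter are under the other observations. The cause of the other changes was not tested.

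The difference in total counts changed direction among the libraries at 0 of the first removed term, with p = 0.384 (exact permutation test). ENSSTOG00000028876 reversed to -0.0705 with limma-voom. With 1 library left out its log2 fold change ranged from 0.30 to 1.87, that of ENSSTOG00000009560 from 0.92 to 1.38, that of ENSSTOG00000009118 from -0.65 to -0.55 and that of ENSSTOG00000014731 from -1.58 to -1.30. Both of the former had their lowest value without disperser replicate 1.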

Other observations

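The tests by splits of the edgeR counts and of the authors' tables, those of the counts with the 5 removed terms and that of the terms' overlap with the groups were chosen after related results were seen. Those of the 2 principal components, limma-voom, resident replicate 8, the overall profile, modules and spread had their bounds written beforehand.

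Splitting the 43 libraries at random into 16 and 27 gave a measure of what chance produces, with 100 splits including the real one. Any split has at least the 0 genes of the real groups at adjusted p 0.05 (100 of 100), so the splits say nothing of that count. At an unadjusted p under 0.05, 62 had at least the real 284 genes. The highest of the other splits had 4707, with 2959 past the threshold. In the authors' normalized values 57 of 100 splits had at least the real 279 (highest other 4911), and in the regressed values 25 had at least the real 730 (highest other 2610). For limma-voom with quality weights it was 20 of 100, against a real 1662 and a highest other of 5636. Chance was not excluded for any of these 4 counts at an unadjusted p under 0.05. The removed terms held 28.9% of the real contrast, against a median of 10.6% over shuffles of the labels. The regressed values thus reduce the real differences more than those of most splits, which tends to raise the 25. The other split with the most genes shared 24.9% of its contrast with the first removed term and 20.3% with the first principal component. Over the other 99 splits the median shares were 0.614% and 1.10%, and the count rose with the share of the first component (Spearman's rho = 0.702 across these splits, which reuse the same libraries). The split with the most genes thus points to a structure of the libraries. A split with 1497 genes shared only 0.0321% with the term and 0.343% with the first component, but 8.57% with the second.

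With 2 principal components as covariates, 2 genes passed adjusted p 0.05, and 69 of 100 splits gave at least as many, with a highest other of 5817 and a median of 214. Of the 99 other splits, 71 called at least 1 gene. The components were taken after the group effect was removed, so they lower the residual spread and leave the group difference largely unadjusted. Most random splits called genes in this fit, so its 2 calls are not evidence of a group difference. How much of the calls in random splits comes from the way the components were taken was not tested.

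The count of small p-values rose from 284 (122 higher, 162 lower) to 1210 (708 higher, 502 lower) when the 5 terms removed by the authors entered the fit. Of 100 splits fitted with the same terms, 10 gave at least as many genes, with a highest other of 2481, so chance was not excluded. The terms held more of the real contrast than of most shuffled ones (28.9% against a median of 10.6%). Most splits thus kept more contrast outside the terms, and how this changed the 10 was not tested. The calls followed GC content, with 198 higher and 19 lower in the class with the lowest GC content and 34 and 152 in that with the highest, and with the GC and length trends removed as offsets these became 124 and 119, and 166 and 125. The count nevertheless rose from 611 to 1445 with the offsets in both fits, which argues against these trends as the whole source of the rise but not as a source of its GC gradient. A group effect shared by the libraries at 0 and at 1 of the first removed term was neither shown nor excluded. Across genes, the group differences at the 2 values correlated at -0.0805, below the median of -0.0334 over 100 shuffles. Of these shuffles, 61 gave a correlation at least as high, so the value gave no sign of a shared effect. The range of the shuffles, -0.36 to 0.35, was wide, so this test cannot exclude such an effect.

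The 5 terms overlapped the groups. They held 28.9% of the group contrast, against a median of 10.6% over 100000 shuffles (permutation p = 0.0241, not adjusted for the other tests here). The 2-valued terms held 2.81% of it, so most of the overlap lay in the continuous terms. What these code is not given in the sources used here, and removing them also removes any group difference that lies along them.

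Without a filter, 265 genes were higher and 1755 lower in dispersers at an unadjusted p under 0.05. Resident replicate 8 had 18929 genes detected at 6395381 counts, against 15178 in the next library, and 1630 genes had counts in that library alone. Without it 446 genes were higher and 436 lower, a ratio of lower to higher of 0.978. The excess of lower genes may come from this library. What set it apart was not tested, and no biological explanation was tested.

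The group accounted for 1.69% of the variance of log2 CPM (permutation p = 0.617) and for 3.50% of that of the authors' normalized values with the 5 terms removed (p = 0.0857), against a 95th percentile of 3.85% over shuffles. In the test with the 5 terms, the shuffled contrasts were not adjusted again for the terms. Their shares are therefore somewhat too low, and that p is too small. Of 10 modules of co-varying genes, built from the 3000 most variable genes of the regressed values, 0 passed an adjusted p of 0.05 (smallest adjusted permutation p = 0.265). The module p-values are too small for the same reason. The median over genes of the log2 ratio of the variance among dispersers to that among residents was 0.074. The central 95% of shuffled values ran from -0.44 to 0.47. The bounds written beforehand took a missed threshold as no shift, which p-values of this size do not show, so a shift was neither shown nor excluded.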
